A study of Mus musculus with 12 samples.

How the data were processed

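The labels describe total RNA from freshly dissected hippocampus of adult mice, with triplicates of WT, Kcnip3 KO, 5xFAD and Kcnip3 KO-5xFAD, so the 12 libraries formed 4 groups of 3. Libraries were made with the TruSeq mRNA kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, HISAT2 2.1.0, featureCounts, R 4.2.1, edgeR 3.38.4 and the mm10 genome build. The strand setting, the annotation release, the version of featureCounts and the gene lengths behind TPM are not given in the sources used here. The deposited table used for every comparison holds raw read counts for 55385 Ensembl genes, and its values are whole numbers. The deposited second table holds log2 TPM for 16120 genes, all those with over 1 CPM (counts per 1e+06 counts of the library) in at least 3 libraries, and the values raised back from log2 sum to the same total in every library. That table served only as an alternative.

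Symbols, positions and transcript sequences came from GENCODE M21, which is on GRCm38, the same assembly as mm10. Of the 55385 genes, 55144 had a symbol and a position there, and the other 241 held 0.00278% of the counts. The libraries held 7664407 to 11310714 counts. A count of 3 corresponded to 0.265 to 0.391 CPM, depending on the library. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

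Before the data were examined, the comparisons, tests, gene lists, named genes and alternative settings were fixed. All 12 libraries were fitted together in edgeR 4.0.16 under R 4.3.3, with 1 coefficient per genotype, TMM scaling, the filterByExpr filter by genotype and a quasi-likelihood test with robust dispersions. Adjusted p-values of genes are Benjamini-Hochberg values from that edgeR test over the 15905 genes tested. A gene was called when its adjusted p was under 0.05, with no minimum fold. The common biological coefficient of variation was 0.144. The contrasts were 5xFAD against WT, Kcnip3 KO against WT, Kcnip3 KO-5xFAD against 5xFAD, Kcnip3 KO-5xFAD against Kcnip3 KO, and the interaction, which is the difference between the 5xFAD effects with and without Kcnip3. Levels are TMM-scaled CPM as mean ± SD, and log2 fold changes are given ± SE.

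The lists of genes held 582 genes, of which 580 were in the table. The 28 lists with at least 5 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with an estimated correlation, and fry, were alternatives. For each list, calls were also counted with p-values adjusted over the list alone. Sex-linked transcripts served only as a check. Medians of lists were also computed with members of 3 or fewer counts in a group set to 3 counts over that group, which left each median as it was.

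Genes were named by a fixed rule. Kcnip3, App and Thy1 were named in every library. In each contrast the rule took the 10 largest positive and 10 largest negative log2 fold changes among called genes whose libraries did not overlap between the groups and whose mean CPM was at least 1. For the interaction it took the 10 called genes with the smallest p. It also took up to 4 called members of each list with the smallest p, or at most 2 members as values where a list had none. Some genes that the plan or the rule takes are not reported here. Other genes named were chosen after their values were seen. These are Trem2, Cst7, Gfap, Eif3j2 and Ttr as values per library, the second copies of called genes, Tgm7, and Fabp7 in the fit of all 12 libraries.

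Called genes within 10 Mb of Kcnip3 were compared with all other tested genes by a two-sided Fisher's exact test. Effects were compared between backgrounds by Pearson's r and Spearman's rho across genes, which are not independent replicates, so no p is given. Genes called in 5xFAD and called with the opposite sign on loss of Kcnip3 were counted and set beside 20 simulations without an effect of Kcnip3. The fit was tested on simulated data with the real design, in which 200 of the genes were changed in 5xFAD. It recovered 26.9% of 1.5-fold, 64.2% of 2-fold and 90.8% of 4-fold changes, with 4% false among 125 calls. With 10 libraries it recovered 19.4%, 66.7% and 89.4%, with 9.38% false among 128 calls. In these simulations no library went against its label and libraries did not differ in quality, so recovery in the data may be lower. When a GC trend was added to the simulated 5xFAD libraries, 40.3% of calls were false without and 2.48% with the length and GC correction described next. A simulated 1.5-fold shift of a list was called at an adjusted p of 2.9e-09, or 0.00278 with an estimated correlation, and 0 of 27 other lists were called by camera.

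Alternative settings fixed then were DESeq2 size factors, library size only, no filter, a stricter filter (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, limma on the deposited log2 TPM, a fit of only the compared groups, the replicate number as a block, non-robust dispersions, a minimum log2 fold change of 1, and leaving out each library. Settings chosen after seeing the data were fits without the libraries labelled WT 3 and Kcnip3 KO-5xFAD 2, without those 2 and Kcnip3 KO 3, and without those 2 and 5xFAD 2. Also chosen then was a correction for transcript length and GC content, with natural splines of 4 degrees of freedom per library as an offset, alone, without those 2 libraries, or with the block. A planned covariate for sex was not run, because Xist was at most 0.284 CPM in every library. Replicate numbers were not taken as pairs. Correlations of same-numbered libraries ran from -0.32 to 0.25, and those of other pairs between groups from -0.38 to 0.29. Of the 12 libraries, 4 were closest to those of their own number. A pairing was thus not shown, and these values do not exclude it. No library was a copy of another: over all pairs the lowest chi-square per gene between the counts of a pair was 4.08, where 1 is expected of reads drawn from the same RNA. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.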

Results

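The series measured gene expression by RNA-seq in the hippocampus of adult mice of 4 genotypes, WT, Kcnip3 KO, 5xFAD and Kcnip3 KO-5xFAD, with 3 libraries each. Kcnip3 encodes KChIP3, also known as DREAM or calsenilin, a calcium-binding protein that modulates Kv4 potassium channels and represses transcription. 5xFAD mice carry mutant human transgenes driven by Thy1 sequences and develop amyloid plaques. The libraries held 7664407 to 11310714 counts, and 15905 genes were tested. P-values weigh a difference between groups against the spread between libraries of the same genotype, estimated over all 4 groups. Whether the libraries of a group are separate animals is not known here.

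Kcnip3 (ENSMUSG00000079056, chromosome 2, 127456498 to 127522094, GRCm38) was lower in every library labelled as knockout than in every library with the intact gene. Its level was 160.0 ± 1.68 CPM in WT, 144 ± 10.5 in 5xFAD, 86.7 ± 33.6 in Kcnip3 KO and 74.6 ± 9.0 in Kcnip3 KO-5xFAD (SD, n = 3). The library labelled Kcnip3 KO 3 held 125 CPM, against 71.4 and 63.4 in the other Kcnip3 KO libraries and at least 138 in the intact libraries. Every library labelled knockout, Kcnip3 KO 3 included, held at least 8.58 CPM of Eif3j2, a gene called below, against at most 0.381 CPM in the intact libraries. Kcnip3 did not pass the test over all genes in Kcnip3 KO (log2 fold change -0.88 ± 0.20, adjusted p = 0.449) or in Kcnip3 KO-5xFAD against 5xFAD (-0.95, adjusted p = 0.245). Without the library labelled Kcnip3 KO 3 it passed in both, at -1.25 and -0.95. Which exons the remaining reads cover was not analysed here.

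Thy1 (ENSMUSG00000032011, chromosome 9), whose sequences drive the transgenes, placed 2 libraries against their labels. Its level was 2870.0, 4236 and 2949 CPM in 5xFAD and 749, 792 and 868 CPM in Kcnip3 KO. In WT it was 747, 887 and 2277 CPM, the last in the library labelled WT 3. In Kcnip3 KO-5xFAD it was 3381, 926 and 2592 CPM, with the low value in the library labelled Kcnip3 KO-5xFAD 2. Trem2, a microglial receptor for lipids, followed the same order, at 22.3, 22.9 and 70.1 CPM in WT and 163, 26.2 and 128 CPM in Kcnip3 KO-5xFAD. Cst7, a cysteine protease inhibitor of plaque-associated microglia, was at 0, 0.319 and 26.5 CPM in WT and at 66.6, 1.00 and 55.9 CPM in Kcnip3 KO-5xFAD. Mouse App was at 1246 ± 54.8 CPM in WT, 1259 ± 11.8 in Kcnip3 KO, 1060.0 ± 87.0 in 5xFAD and 1055 ± 73.8 in Kcnip3 KO-5xFAD. All groups were kept as labelled, and each count was also computed without these 2 libraries, a choice made after their levels were seen.

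**Figure D1:**
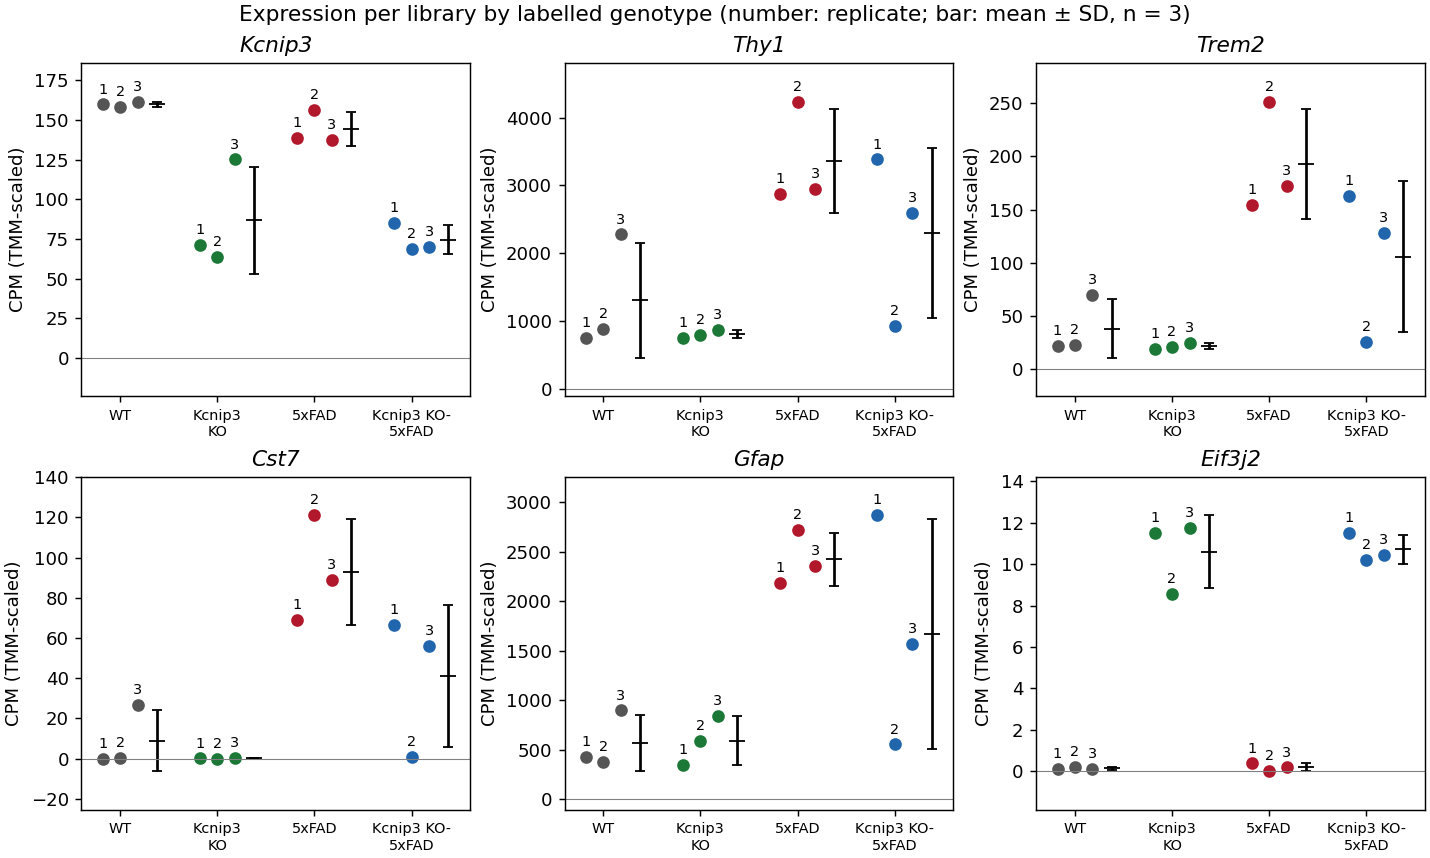
TMM-scaled CPM of Kcnip3, Thy1, Trem2, Cst7, Gfap and Eif3j2 in each library by labelled genotype, with bars for the mean ± SD of 3 libraries. Thy1 is at 2277 CPM in the library labelled WT 3 and at 926 CPM in the library labelled Kcnip3 KO-5xFAD 2, and Kcnip3 is at 125 CPM in the library labelled Kcnip3 KO 3.

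5xFAD against WT compares the groups labelled with and without the transgenes where Kcnip3 is intact, with the library labelled WT 3 in the latter. Several transcripts of microglia and complement rose, while no list passed with an estimated correlation and all 12 libraries. Cd9, a tetraspanin, rose from 45.4 ± 2.65 to 118 ± 10.6 CPM (log2 fold change 1.38 ± 0.17, adjusted p = 0.0104). Apoe, the main lipid carrier of the brain, rose from 2882 ± 207 to 5445 ± 1117 CPM (0.92 ± 0.15, adjusted p = 0.0173). Clu, the extracellular chaperone clusterin, rose from 1145 ± 30.2 to 2029 ± 260.5 CPM (0.83 ± 0.11, adjusted p = 0.0104). Snap25, a SNARE protein of synaptic vesicle release, fell from 1445 ± 139 to 887 ± 71.7 CPM (-0.70 ± 0.11, adjusted p = 0.0173).

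Of the 28 genes of plaque-associated microglia, 28 had a higher mean in 5xFAD and 12 rose, among them Cd9, Cd63 (0.88), Apoe and Lgals3 (1.81). Adjusted over the list alone, 25 rose. The median log2 fold change was 1.74 and camera gave an adjusted p of 3.8e-17, with an adjusted p = 0.399 with an estimated correlation. Of the 14 homeostatic microglial genes 9 rose, such as Olfml3 (1.25), Selplg (1.03), Fcrls (1.30) and Tmem119 (0.65), with 11 adjusted over the list alone. Their median was 0.96 (camera adjusted p = 5.2e-09, adjusted p = 0.399 with an estimated correlation). Of the 23 genes of complement and antigen presentation 9 rose, including the C1q subunits C1qa (1.84), C1qb (1.76) and C1qc (1.76) and the Fc receptor chain Fcer1g (1.68), with 18 adjusted over the list alone. The median of that list was 1.28 (camera adjusted p = 1.1e-11, adjusted p = 0.399 with an estimated correlation). The reactive astrocyte list had a median of 0.61 and 1 called member of 25, the immunoproteasome subunit Psmb8 (1.13). It passed camera at 0.00018, with an adjusted p = 0.461 with an estimated correlation. Interferon response genes were higher in 21 of 23 cases with a median of 0.66 (camera adjusted p = 0.013, adjusted p = 0.654 with an estimated correlation). Gpnmb (2.98), Treml2 (2.82), Gpr84 (2.60), Cd52 (2.50), Milr1 (2.21), Slc15a3 (2.19) and Bcl2a1b (2.13) were among the largest increases. Gm12751, a processed pseudogene on chromosome 4, was at 3.94, 3.69 and 3.71 CPM in 5xFAD and at 0.106, 0 and 0 CPM in WT.

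Of the 27 activity-regulated genes 24 had a lower mean in 5xFAD, and the phosphatase gene Dusp1 fell from 55.6 ± 12.4 to 24.1 ± 9.28 CPM. The median was -0.81, and 12 fell when adjusted over the list alone (camera adjusted p = 4.4e-06, adjusted p = 0.461 with an estimated correlation). Of the 35 genes of excitatory synapses and long-term potentiation 4 fell: Snap25, the phospholipase Plcb1 (-0.65), the postsynaptic adhesion protein Nlgn1 (-0.67) and the transcription factor Creb1 (-0.64). The list had a median of -0.05 and did not pass camera (adjusted p = 0.22). Other transcripts that fell were the synaptic adhesion gene Il1rapl1 (-1.61), the sialyltransferase St6gal2 (-1.41), Zfp367 (-1.19), Naa30 (-1.19), the cholinesterase Bche (-1.18), Cbln4 (-1.17), the interneuron receptor Erbb4 (-0.74) and the calcium pump Atp2a2 (-0.45). The genes that fell had a median transcript length of 4856.5 nucleotides and 43.0% GC, against 2043.5 nucleotides and 53.4% GC for those that rose and 3273 nucleotides and 49.9% GC for all tested genes.

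Camera called 12 of 28 lists in this comparison. In all, 304 genes rose and 258 fell, out of 4030 with an unadjusted p under 0.05, and 560 of the 562 did not overlap between the groups. Chance gives that pattern in 10% of unselected genes with 3 against 3. The calls were made on the same libraries, so the lack of overlap is no separate support. Mitochondrial genes held 3.58% to 3.74% of the counts in 5xFAD and 3.84% to 5.10% in WT. The library labelled 5xFAD 2 had the fewest genes with counts (21673). Whether such differences between libraries contribute to the calls was not tested. The numbers of called genes rested on particular libraries. Leaving out the library labelled WT 1, 5xFAD 2 or 5xFAD 3 left 1 called gene each time, a higher one. Without the library labelled WT 3 they were 12 higher and 1 lower, and without 5xFAD 1 they were 939 and 1178. Without the library labelled Kcnip3 KO-5xFAD 3, which serves only to estimate the spread, they were 143 and 89. Without WT 2, 147 were higher, and without Kcnip3 KO-5xFAD 1, 168 were lower. With the length and GC correction 67 rose and 31 fell, of which 58 and 29 were among the original calls.

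Without the libraries labelled WT 3 and Kcnip3 KO-5xFAD 2, 196 genes rose and 13 fell in 5xFAD against WT, and 141 of these were also called with all 12. Because the 2 libraries were left out for their Thy1 and microglial levels, the microglial calls below are not independent of that choice. Plaque-associated microglial genes rose in 22 of 28 cases with a median of 1.95, and this list passed with an estimated correlation (adjusted p = 0.0296). Itgax, an integrin of activated microglia, rose by 6.17 ± 0.39 (adjusted p = 8.3e-06), Trem2 by 3.09 ± 0.22 and its adaptor Tyrobp by 2.90 ± 0.22. Cst7 rose to 93.0 ± 26.3 CPM in 5xFAD from 0 and 0.319 CPM in the remaining WT libraries. The chemokine genes Ccl4 (5.16), Ccl3 (4.45) and Ccl6 (3.44) and the receptor genes Hcar2 (4.87) and Clec7a (4.38) were further large increases. Genes of complement and antigen presentation rose in 13 of 23 cases (median 1.34, adjusted p = 0.0296 with an estimated correlation), and homeostatic microglial genes in 9 of 14, such as Csf1r (1.23), with an adjusted p = 0.0924 with an estimated correlation. Among reactive astrocyte genes the intermediate filament gene Gfap rose from 401 ± 36.7 (n = 2) to 2423 ± 270.5 CPM. Snap25 fell by 0.67 and the calcium channel subunit gene Cacnb4 by 0.69, while Dusp1 (-1.35, adjusted p = 0.0518) and Plcb1 (-0.55, adjusted p = 0.114) did not pass. With the library labelled 5xFAD 2 left out as well, 146 rose and 2 fell, and with Kcnip3 KO 3 left out instead, the adjusted p of the lists with an estimated correlation was at least 0.0767.

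Kcnip3 KO against WT compares the groups labelled with and without the knockout among those labelled without the transgenes, with the library labelled WT 3 in the WT group and Kcnip3 KO 3 in the other. With edgeR and its filter the called genes were few, and most lay near Kcnip3 on chromosome 2 or were copies of genes there. With DESeq2 9 of 29 called genes lay within 10 Mb of Kcnip3, and with edgeR and no filter 14 of 324. Eif3j2 (ENSMUSG00000043424, chromosome 18), a copy of a translation initiation factor subunit gene, rose from 0.141 ± 0.0619 to 10.6 ± 1.76 CPM (6.10 ± 0.40, adjusted p = 4.2e-06). Pla2g4e (ENSMUSG00000050211, chromosome 2), a calcium-dependent phospholipase gene, rose from 12.1 ± 1.91 to 55.0 ± 10 CPM (2.19 ± 0.17, adjusted p = 2.3e-05). Eif3j1, the second copy of the initiation factor gene, fell from 27.1 ± 4.19 to 9.73 ± 0.784 CPM (-1.48 ± 0.15, adjusted p = 0.000382).

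The other called genes were Pcna-ps2 (3.50), Mfap1b (-1.47), the augmin subunit Haus2 (-1.14), the leucine-breakdown enzyme Ivd (-0.86) and Gm3650, a pseudogene beside Eif3j2. Gm3650 was at 5.96, 5.92 and 7.25 CPM in Kcnip3 KO and at 0.213, 0 and 0 CPM in WT. The libraries of the groups did not overlap for any of the 8, as chance gives in 10% of unselected genes. The calls used the same libraries, so the lack of overlap is no separate support. In all, 718 genes had an unadjusted p under 0.05, no more than the share of 0.05 of the 15905 tested genes that chance gives. Of the 8, 5 lay within 10 Mb of Kcnip3, where 213 genes were tested (Fisher's exact test, two-sided, p = 2.2e-08), at distances of 5.40 to 8.57 Mb, so that with a window of 5 Mb p was 1. Summed over both copies, Eif3j1 and Eif3j2 gave 19.9 CPM on average in the 6 libraries labelled knockout and 25.3 CPM in the 6 intact libraries. Counts of lower genes were 9 without the library labelled Kcnip3 KO 2 and 7 without Kcnip3 KO-5xFAD 2, against 4 in all. Ivd did not pass without the library labelled WT 2 (-0.81) or Kcnip3 KO 1 (-0.87), nor without the 2 libraries against their labels (-0.89), where 4 genes rose and 3 fell.

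**Figure D2:**
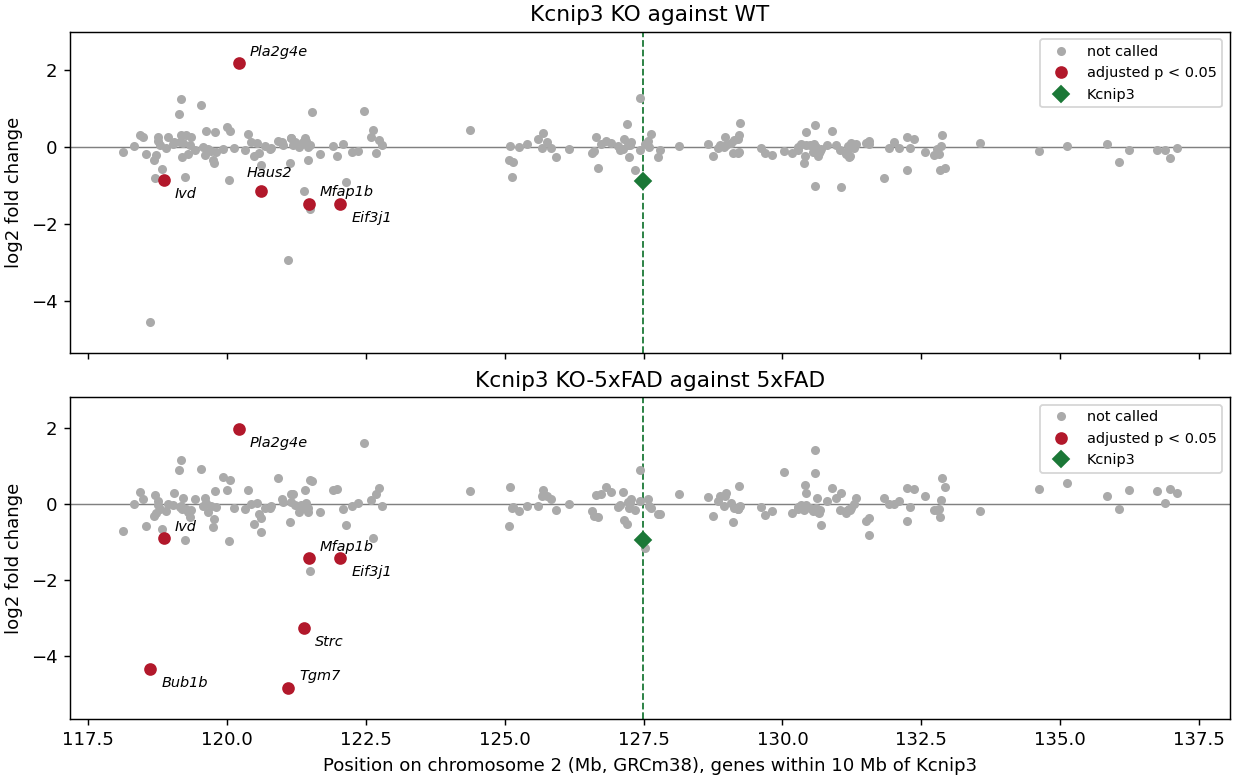
Log2 fold change of each tested gene within 10 Mb of Kcnip3 against its position on chromosome 2, for Kcnip3 KO against WT and for Kcnip3 KO-5xFAD against 5xFAD. Red points are called genes (5 and 7), all at lower positions than Kcnip3 (the green diamond), 5.40 to 8.82 Mb from it.

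No list had a member called over all genes in Kcnip3 KO. Activity-regulated genes had a median of -0.37, with 21 of 27 lower and 12 that fell when adjusted over the list alone (camera adjusted p = 2.9e-11, adjusted p = 0.443 with an estimated correlation). Examples are Dusp1 (-1.20, adjusted p = 0.449 over all genes) and the transcription factor Egr4 (-1.32, adjusted p = 0.449). Reported KChIP3 (DREAM) targets, of which 5 of 15 are also in the activity-regulated list, had a median of -0.14 and 4 members that fell when adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.443 with an estimated correlation). Fos, a DREAM target and immediate early gene, was at 46.6 ± 9.14 CPM in WT and 12.4 ± 3.93 CPM in Kcnip3 KO (-1.91, adjusted p = 0.458). Interferon response genes were lower in 23 of 23 cases, with a median of -0.79 (adjusted p = 0.603 with an estimated correlation), and complement and antigen presentation genes in 22 of 23, with a median of -0.44 (adjusted p = 0.574). The median of the complement list without the 2 libraries against their labels was -0.20 with 18 of 23 lower, that of the interferon list -0.65, and that of the DREAM targets -0.09, where the latter did not pass camera. B2m, the light chain of MHC class I, was at 60.0 ± 4.51 against 114 ± 16.9 CPM (-0.92, adjusted p = 0.999), and it lies within 10 Mb of Kcnip3. Myelin genes had a median of 0.51, with 21 of 21 higher (adjusted p = 0.457 with an estimated correlation). Camera called 11 of 28 lists in all, and 6 without the library labelled WT 3.

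Kcnip3 KO-5xFAD against 5xFAD addresses the question in the series title, what loss of Kcnip3 does in the presence of the transgenes. With edgeR and its filter the calls were again mostly genes around Kcnip3, while 8 of 29 calls with DESeq2 and 19 of 351 with edgeR and no filter lay within 10 Mb. Eif3j2 rose from 0.187 ± 0.191 to 10.7 ± 0.702 CPM (5.70 ± 0.39, adjusted p = 7.3e-06) and Pla2g4e from 11.7 ± 2.24 to 46.6 ± 3.79 CPM (1.98 ± 0.17, adjusted p = 7.9e-05). Eif3j1 fell from 23.2 ± 0.315 to 8.67 ± 1.30 CPM (-1.42 ± 0.15, adjusted p = 0.000634). In all 5 genes rose and 6 fell, out of 1649 with an unadjusted p under 0.05. None of the called genes overlapped between groups (10% of unselected genes by chance), which calls on the same libraries nearly fix. Of these, 4 higher and 3 lower genes were also called in Kcnip3 KO against WT, where independent calls would share 0.00126 and 0.00151.

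Genes called only in this contrast were Strc, the gene of the inner-ear protein stereocilin (-3.26), the mitotic checkpoint kinase gene Bub1b (-4.35), Lbhd2 on chromosome 12 (3.85) and the transglutaminase gene Tgm7, at 1.52, 1.70 and 1.27 CPM in 5xFAD and 0.111, 0 and 0 CPM in Kcnip3 KO-5xFAD. In Kcnip3 KO against WT, Bub1b (-4.57), Tgm7 (-2.93) and Strc (-1.15) were also lower but not called. Whether the effects on the genes called only in this contrast differ between the backgrounds was not shown, since the interaction called none of them. Of the 11, 7 lay within 10 Mb of Kcnip3 (Fisher's exact test, two-sided, p = 2.2e-11), and with a window of 5 Mb p was 1. Fewer lay there without the 2 libraries against their labels (2 of 6, Fisher's exact test, two-sided, p = 0.0026) and without those and 5xFAD 2 (2 of 7, Fisher's exact test, two-sided, p = 0.0036). Strc and Bub1b did not pass without the library labelled 5xFAD 1, 5xFAD 3, Kcnip3 KO-5xFAD 1, Kcnip3 KO-5xFAD 2 or Kcnip3 KO-5xFAD 3, with log2 fold changes of -3.44 to -3.15 and -5.62 to -3.79. Lbhd2 did not pass without WT 2, any 5xFAD library, Kcnip3 KO-5xFAD 2 or Kcnip3 KO-5xFAD 3 (3.45 to 4.18), and Ivd did not without 5xFAD 3 (-0.86) or Kcnip3 KO-5xFAD 3 (-0.84). The number of lower genes was 3 without 5xFAD 1, Kcnip3 KO-5xFAD 1 or Kcnip3 KO-5xFAD 2, and 2 without 5xFAD 3 or Kcnip3 KO-5xFAD 3.

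Plaque-associated microglial genes had a median of -0.66 in Kcnip3 KO-5xFAD against 5xFAD with 27 of 28 lower (camera adjusted p = 3.1e-09), and an adjusted p = 0.818 with an estimated correlation. edgeR called 0 of them, over all genes or adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05. Complement and antigen presentation had a median of -0.41 and nuclear-encoded oxidative phosphorylation of -0.16, while activity-regulated genes had a median of 0.30 with 26 of 27 higher (adjusted p = 0.818 with an estimated correlation for each). The library labelled Kcnip3 KO-5xFAD 2, with Trem2 at 26.2 CPM, is part of these medians. Without the 2 libraries against their labels the plaque-associated median was -0.31 and that of complement -0.03. In that fit 5 genes rose and 1 fell. The added call was Fabp7, a fatty acid binding protein of radial glia and astrocytes, at 26.7 ± 4.57 CPM in 5xFAD and 68.4 ± 7.77 CPM in Kcnip3 KO-5xFAD (n = 2; 1.36 ± 0.18, adjusted p = 0.00835). With all 12 libraries Fabp7 had a log2 fold change of 1.13 (adjusted p = 0.153). Cholesterol synthesis genes did not pass with all 12 libraries (median 0.19, camera adjusted p = 0.0985). In the fit without the 2 they had a median of 0.31, and 7 of 19 rose when adjusted over the list alone (camera adjusted p = 3.4e-06, adjusted p = 0.954 with an estimated correlation). Camera called 6 of 28 lists with all 12 libraries, 11 without the library labelled 5xFAD 2 and 10 without Kcnip3 KO-5xFAD 1.

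Kcnip3 KO-5xFAD against Kcnip3 KO compares the groups labelled with and without the transgenes on the knockout background, with the library labelled Kcnip3 KO-5xFAD 2 in the former. Plaque-associated microglial genes were higher in 27 of 28 cases with a median of 1.54, and 26 rose when adjusted over the list alone (camera adjusted p = 5.4e-19, adjusted p = 0.246 with an estimated correlation). Genes of complement and antigen presentation were higher in 23 of 23 cases (median 1.43, 22 adjusted over the list alone, adjusted p = 0.246 with an estimated correlation). Interferon response genes were higher in 23 of 23 (median 1.71, 15 adjusted over the list alone, adjusted p = 0.328 with an estimated correlation). Over all genes edgeR called 0 with all 12 libraries, with 1657 at an unadjusted p under 0.05 and a lowest adjusted p of 0.154. limma-voom and limma on log2 TPM also called 0, while DESeq2 called 111 higher and 24 lower. Without the library labelled Kcnip3 KO-5xFAD 2, 190 rose and 3 fell. Without Kcnip3 KO 2, 3 rose, and without Kcnip3 KO-5xFAD 3, 1 fell.

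Without the 2 libraries against their labels 208 genes rose and 1 fell in Kcnip3 KO-5xFAD against Kcnip3 KO, with the same dependence on the choice of libraries as above. Itgax rose by 6.47 ± 0.38 (adjusted p = 4.6e-06), the phagocytic receptor gene Clec7a by 5.69 ± 0.50, the lysozyme gene Lyz2 by 2.64 ± 0.19 and the cathepsin gene Ctsz by 1.91 ± 0.14. Cst7 was at 66.6 and 55.9 CPM against 0.105, 0 and 0.230 CPM. Of the plaque-associated genes 20 of 28 rose (median 1.90, adjusted p = 0.0187 with an estimated correlation), and of complement and antigen presentation 19 of 23 (median 1.71, adjusted p = 0.0120). Of the interferon response genes 10 of 23 rose (median 2.12, adjusted p = 0.145 with an estimated correlation). They include Bst2 (2.25), Ifi27l2a (3.78), Ifitm3 (1.64) and Mx1, at 3.99 and 1.96 CPM against 0.209, 0 and 0.115 CPM. B2m rose by 1.80 ± 0.14 and Gfap by 1.91 ± 0.35. Lgi2, a secreted neuronal protein gene, fell from 105 ± 4.37 to 65.9 ± 7.63 CPM (-0.67 ± 0.14, adjusted p = 0.0286). With Kcnip3 KO 3 left out as well, 157 rose and 3 fell, and with an estimated correlation complement and antigen presentation passed (adjusted p = 0.0445) while the plaque-associated list did not (adjusted p = 0.0532).

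**Figure D3:**
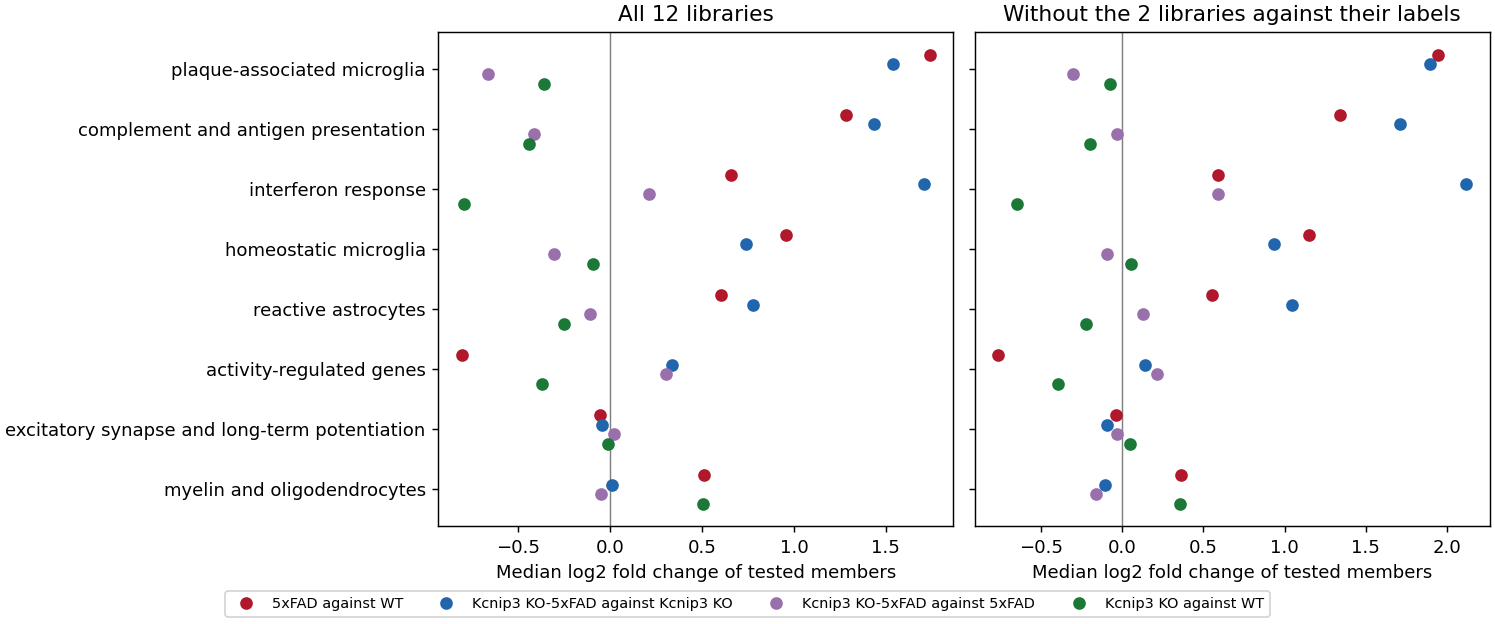
Median log2 fold change of 8 gene lists in 4 contrasts, with all 12 libraries and without the 2 libraries against their labels. In 5xFAD against WT the plaque-associated microglia median is 1.74 with all 12 and 1.95 without the 2, and in Kcnip3 KO-5xFAD against 5xFAD it is -0.66 and -0.31.

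The interaction tests whether the 5xFAD effect differs with Kcnip3. In the fit without the 2 libraries Fabp7 was the only call (1.99 ± 0.25, adjusted p = 0.0417). It also passed with 5xFAD 2 left out as well (2.13, adjusted p = 0.0168). It did not pass with Kcnip3 KO 3 left out instead (1.96, adjusted p = 0.203) or with all 12 libraries (1.80, adjusted p = 0.430). Nor did it with the length and GC correction and without the 2 libraries (1.88, adjusted p = 0.0549). It was at 34.7 ± 2.33 CPM in WT (n = 2), 26.7 ± 4.57 in 5xFAD, 22.5 ± 4.90 in Kcnip3 KO and 68.4 ± 7.77 in Kcnip3 KO-5xFAD (n = 2). With all 12 libraries edgeR called 0 genes, with 836 at an unadjusted p under 0.05 and a lowest adjusted p of 0.430. Chance gives such a p in a share of 0.05 of the 15905 tested genes, and 836 is close to that. limma-voom and limma on log2 TPM called 0, and DESeq2 called 5 higher and 1 lower. Without 1 library, 4 were higher leaving out 5xFAD 1, 3 leaving out Kcnip3 KO 2 and 1 leaving out Kcnip3 KO-5xFAD 2, and 1 was lower leaving out Kcnip3 KO 1 or Kcnip3 KO-5xFAD 3. Activity-regulated genes had a median interaction of 0.93, with 11 of 27 passing when adjusted over the list alone (camera adjusted p = 3.8e-11, adjusted p = 0.402 with an estimated correlation). Fos had the smallest p among them, at 2.81 ± 0.59 (adjusted p = 0.853). Interferon response genes had a median of 0.91 (adjusted p = 0.795 with an estimated correlation). These medians were 0.61 and 1.48 without the 2 libraries. For activity-regulated genes the same WT libraries are the reference for the medians of -0.81 in 5xFAD against WT and -0.37 in Kcnip3 KO against WT. Those libraries also enter the interaction, so these results on activity-regulated genes are not independent of each other.

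Across the 15905 genes, the 5xFAD effects with and without Kcnip3 correlated at r = 0.394 and rho = 0.433, and the effects of losing Kcnip3 with and without the transgenes at r = 0.101 and rho = 0.0747. The latter pair of effects had r = 0.133 and rho = 0.181 without the 2 libraries against their labels, 0.182 and 0.254 with Kcnip3 KO 3 left out as well, and 0.261 and 0.319 without the 2 alone at a mean CPM of at least 10. With all others kept, its r was 0.0150 without the library labelled WT 2 and 0.0208 without Kcnip3 KO 1. It was 0.164 without WT 3 or Kcnip3 KO 3, 0.16 without 5xFAD 3 and 0.176 without Kcnip3 KO-5xFAD 1. Without the 2 libraries against their labels, 144 genes rose with the transgenes in both backgrounds, where independent calls would share 2.54. That overlap depends on leaving out the 2 libraries, which were chosen for their Thy1 and microglial levels. With all 12 libraries 0 genes were shared, since 0 were called on the knockout background. These values are across genes, which are not independent replicates.

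Reversal of the transgene effect was looked for among the 562 genes called in 5xFAD against WT. In Kcnip3 KO-5xFAD against 5xFAD edgeR called 0 of them with the opposite sign and 0 with the same sign, and DESeq2 called 12 of its own with the opposite sign. At an unadjusted p under 0.05, 315 of the 562 (56.1%) had the opposite sign. In simulations without an effect of Kcnip3, where the shared 5xFAD libraries alone give such pairs, 175 of 2213 called genes did on average (150 to 191). Without the 2 libraries against their labels it was 38 of 209 genes (18.2%), against 79 to 108 of 1206 called on average. By count the data lay above every simulation with all 12 libraries and below every one without the 2, and by share above their average both times (7.92% and 7.98%). The simulations called more genes than the data, so neither decides and reversal is not shown. Leaving out 5xFAD 2 as well gave 8 of 148 (5.41%). The adjusted count was 1 without the library labelled Kcnip3 KO 1, Kcnip3 KO 2 or 5xFAD 1.

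**Figure D4:**
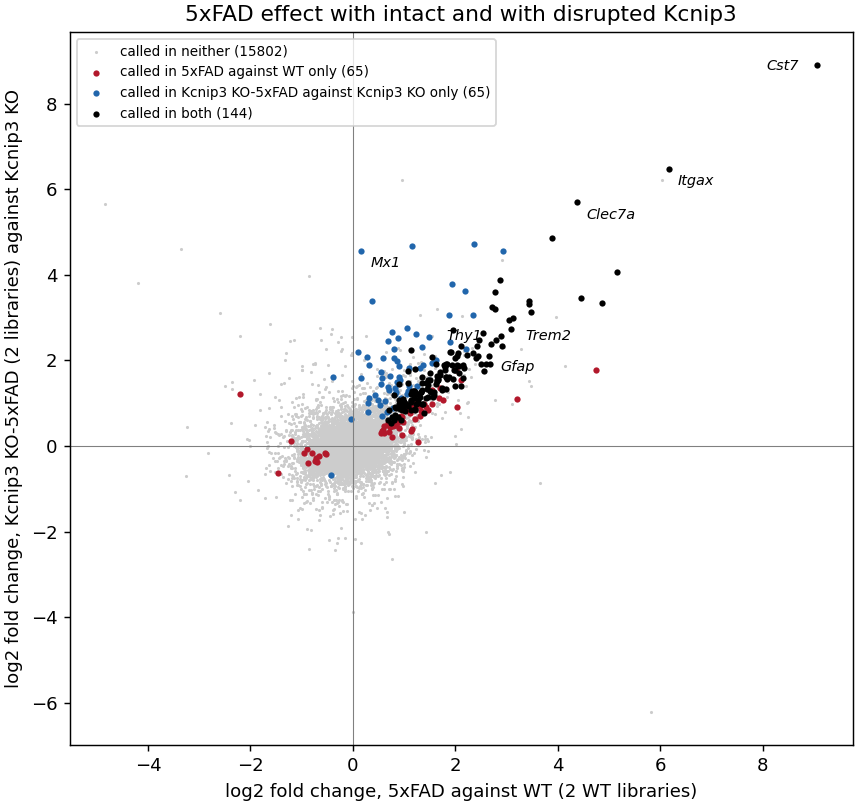
Log2 fold change of 5xFAD against WT on the horizontal axis and of Kcnip3 KO-5xFAD against Kcnip3 KO on the vertical axis for each tested gene, without the 2 libraries against their labels. Of the called genes 144 rose in both contrasts, and 65 were called in each contrast alone.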

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

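Of the tests in this part, those of the interaction with all 12 libraries were planned, and that of the genes lower in 5xFAD in the other Kcnip3 background was written before its result was seen; the fits without named libraries or with the length and GC correction, the other tests of explanations and the counts of splits were chosen after the results were seen.

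Camera on the interaction called 10 lists with all 12 libraries, but with an estimated correlation none of the 10 passed (lowest adjusted p = 0.197), and fry called 0. They are given by their median log2 fold change. Activity-regulated genes had 0.93, reported KChIP3 (DREAM) targets 0.24, interferon response genes 0.91, meninges and fibroblasts 0.69, blood cells 0.75 and adult neurogenesis 0.22. Choroid plexus had -1.84, myelin and oligodendrocytes -0.46, nuclear-encoded oxidative phosphorylation -0.17 and plaque-associated microglia -0.12. The plaque-associated list passed as lower although its mean was 0.21. The medians of activity-regulated genes, interferon response, blood cells and choroid plexus without the 2 libraries against their labels were 0.61, 1.48, 0.14 and -1.04, and the last 2 of these lists did not pass camera. Fabp7 passed in that fit, with an interaction of 1.99, and with 5xFAD 2 left out as well (adjusted p = 0.0168). It did not pass with Kcnip3 KO 3 left out instead (adjusted p = 0.203). Nor did it with the length and GC correction and without the 2 libraries (adjusted p = 0.0549). Of 100 splits of the 12 libraries, the real one included, 55 gave at least the 10 lists called for the interaction and the highest gave 16. The other splits mix libraries of all genotypes, so effects of the transgenes and of the knockout enter them. They are thus no measure of chance for the interaction alone, and chance is not excluded for the lists. For genes edgeR called 0, which any split reaches, so the splits decide nothing. The highest split gave 796 and points to a structure of the samples, since its contrast set the 6 libraries labelled without the transgenes against the 6 labelled with them.

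The libraries labelled WT 3 and Kcnip3 KO-5xFAD 2 had Thy1 and microglial genes against their labels. The tables argue against an exchange of the 2 libraries, since WT 3 held 162 CPM of Kcnip3, as in the other WT libraries. They also argue against RNA of any of the 5 other sequenced libraries with the transgenes mixed into WT 3. Its Thy1 would need a larger share of the donor than 20 plaque-associated genes, by at least 16.8 percentage points over their upper quartile. Those genes were the list members called higher in Kcnip3 KO-5xFAD against Kcnip3 KO without the 2 libraries. WT 3 was nearer to the 5xFAD mean in 23.6% of 208 called genes, which argues against a library like those of the 5xFAD group, and leaves open a donor that was not sequenced or an animal with the transgenes and a smaller response. Kcnip3 KO-5xFAD 2 was nearer to the Kcnip3 KO mean in 89.8% of 196 genes called higher in 5xFAD. Among the 144 of these outside the gene lists the share was 88.2%. This library was singled out for its low Thy1 and microglial genes, so both shares are not independent of that choice. Of the 13 genes called lower, the share was 0%. A library like those of Kcnip3 KO thus stays open, as does an animal that lost the transgenes.

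Genes called on loss of Kcnip3 by edgeR with its filter and all 12 libraries lay near it or were copies of genes there in both backgrounds, except Gm3650, which lies beside the copy Eif3j2, and Lbhd2. Of the DESeq2 calls 9 of 29 and 8 of 29 lay within 10 Mb. DNA of another strain kept around the knockout and an effect of losing Kcnip3 on its neighbours cannot be told apart, because no library here separates flanking DNA from the loss of Kcnip3. The Fisher p for calls within 10 Mb, 2.2e-08 as the larger of the 2 backgrounds and 1 with a window of 5 Mb, restates the pattern and supports neither; without the 2 libraries against their labels it was 0.0026 in Kcnip3 KO-5xFAD against 5xFAD, with 2 calls there in place of 7. Reads moved between near-identical copies may account for part of the change of Eif3j1. The log2 ratio of knockout to intact libraries was -0.34 for the sum of Eif3j1 and Eif3j2 against -1.45 for Eif3j1 alone. For Pcna with Pcna-ps2 it was -0.16 against -0.52 for Pcna alone. For Mfap1a with Mfap1b it was -0.31 against -1.46 for Mfap1b alone. Mfap1a itself was not called in Kcnip3 KO against WT (0.04), so no gain of reads by it was seen there. A sum with an unchanged copy falls less whether or not reads move, so the ratio for Mfap1b does not decide it.

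Genes that fell in 5xFAD against WT were long and low in GC content. After the length and GC correction their median log2 fold change was -0.41, from -0.63 before, with a median SE of 0.12 and 0.15, and 29 of the 258 stayed called; the fold became smaller while the median SE did not grow. The correction lowered the change and left most of it, so the trend with length and GC as part of the cause cannot be told apart from an effect of the genotype, because the rank correlation of a library's deviation from the mean log expression with GC content was 0.136, 0.407 and 0.397 in 5xFAD and -0.286, 0.136 and -0.355 in WT. In Kcnip3 KO-5xFAD against Kcnip3 KO, corrected and without the 2 libraries against their labels, the same genes had a median of -0.13. The upper quartile was -0.0478 and the median SE 0.13. Median and upper quartile were negative, as predicted for an effect of the transgenes on these genes in both backgrounds. The median change was no larger than the median SE, and genes are not independent replicates, so these values do not decide it. The size cannot be compared, since the genes were chosen by their calls in 5xFAD against WT.

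Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. For 5xFAD against WT the real split gave 562 genes and the highest other 0 with edgeR, and 12 against 13 lists, with 1 and 3 of the splits giving as many. For Kcnip3 KO against WT they were 8 against 0 genes and 11 against 11 lists, with 1 and 3 splits giving as many. For Kcnip3 KO-5xFAD against 5xFAD they were 11 against 13 genes and 6 against 13 lists, with 2 and 10 splits giving as many; the split with 13 set 5xFAD 1, 5xFAD 3 and Kcnip3 KO-5xFAD 3 against the rest. For Kcnip3 KO-5xFAD against Kcnip3 KO they were 0 against 1 gene and 12 against 12 lists, with 10 and 2 splits giving as many.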

How the results depend on the processing

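The fits without particular libraries by name and the length and GC correction were chosen after seeing the data; the other alternatives were planned. Over all alternatives, 1414 of 1993 values of named genes kept their direction and side of the threshold, 553 kept the direction only, 21 newly passed and 5 changed sign. Of 1173 values of the lists that camera called with all 12 libraries, 946 kept both. The other 227 did not pass, and their direction was not counted. Unless stated, the cause of a change was not tested. The depth of 7664407 to 11310714 counts limits what is seen of genes near 3 counts, and the covariate for sex was not run.

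Counts are given as higher and lower genes. For 5xFAD against WT (304 and 258) they were 1136 and 995 with no filter, 667 and 764 with DESeq2, 632 and 602 with the replicate block, 6 and 2 with limma on log2 TPM, and 105 and 24 with a minimum log2 fold change of 1, which removes calls by its construction. They were 196 and 13 without the 2 libraries against their labels, 146 and 2 without those and 5xFAD 2, 67 and 31 with the length and GC correction, 185 and 9 with it and without the 2 libraries, and 64 and 42 with it and the block. With library size only 202 were higher, with only the compared groups 119 were lower, and without the 2 libraries and Kcnip3 KO 3, 13 were lower. Leaving out 1 library gave 1 to 939 higher and 0 to 1178 lower. Of the called genes 54.1% were higher with TMM, 50.7% with DESeq2 size factors and 43.3% with library size only, and the median of all genes lay between -0.06 and 0.05 under each.

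For Kcnip3 KO against WT (4 and 4) the counts were 203 and 121 with no filter and 9 and 20 with DESeq2, 10 were lower with only the compared groups, and leaving out 1 library gave 4 to 5 higher and 3 to 9 lower. For Kcnip3 KO-5xFAD against 5xFAD (5 and 6) they were 200 and 151 with no filter and 16 and 13 with DESeq2. Lower genes there were 1 without the 2 libraries, 2 without those and 5xFAD 2, 3 with the correction and without the 2, and 3 with the stricter filter. Leaving out 1 library gave 4 to 5 higher and 2 to 7 lower. For Kcnip3 KO-5xFAD against Kcnip3 KO (0 and 0 with edgeR, 1657 at an unadjusted p under 0.05) they were 419 and 302 with no filter, 111 and 24 with DESeq2, 208 and 1 without the 2 libraries, 211 and 5 without those and 5xFAD 2, 157 and 3 without those and Kcnip3 KO 3, and 209 and 5 with the correction and without the 2. Leaving out 1 library gave 0 to 190 higher and 0 to 3 lower. For the interaction (0 and 0 with edgeR, 836 at an unadjusted p under 0.05, close to what chance gives) they were 144 and 128 with no filter and 5 and 1 with DESeq2. Higher genes there were 1 with the block and 1 with the correction and the block, Eomes in both, 1 without the 2 libraries and 1 without those and 5xFAD 2, but 0 without those and Kcnip3 KO 3 (lowest adjusted p = 0.203) and 0 with the correction and without the 2 (0.0549), and leaving out 1 library gave 0 to 4 higher and 0 to 1 lower. Of the calls with no filter, 2096 of 2131, 281 of 324, 342 of 351, 668 of 721 and 263 of 272 in the order above were genes that the filtered fit also tested.

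Lists called by camera were 12, 11, 6, 12 and 10 in that order. With an estimated correlation there were 0 in each contrast, and with fry 4, 0, 1, 0 and 0. The length and GC correction gave 11 in Kcnip3 KO-5xFAD against 5xFAD. Leaving out 1 library gave 10 to 13, 6 to 14, 6 to 11, 9 to 13 and 8 to 11.

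The correlation of the 5xFAD effect between backgrounds (0.394) was 0.0608 with no filter, 0.442 with log2 TPM, 0.558 with the stricter filter, 0.572 at a mean CPM of at least 10 and 0.452 without the 2 libraries and Kcnip3 KO 3, and 0.286 to 0.437 leaving out 1 library. That of the Kcnip3 effect (0.101) was 0.0122 with no filter, 0.204 with the stricter filter and 0.182 without the 2 libraries and Kcnip3 KO 3, and 0.0150 to 0.176 leaving out 1 library. The neighbourhood p was 1 in both backgrounds with a window of 5 Mb, where no called gene lies, and 2.3e-11 to 1.1e-06 and 8.5e-12 to 4.7e-05 leaving out 1 library. In Kcnip3 KO-5xFAD against 5xFAD it was 0.0026 without the 2 libraries and 0.0036 without those and 5xFAD 2. Genes of 5xFAD called with the opposite sign on loss of Kcnip3 (0 with edgeR) were 245 with no filter, 12 with DESeq2, 315 at an unadjusted p, and 1 each with log2 TPM, limma-voom, the block, the correction with the block, and without the 2 libraries and Kcnip3 KO 3. Leaving out 1 library gave 0 to 1. The log2 fold change of Kcnip3 in Kcnip3 KO-5xFAD against Kcnip3 KO (-0.22) was -0.40 to 0.14 leaving out 1 library, the latter without Kcnip3 KO replicate 3, and 0.20 without it and the 2 libraries. That of Thy1 was 0.059 in Kcnip3 KO against WT with the correction and without the 2 libraries, and in Kcnip3 KO-5xFAD against 5xFAD it was 0.00103 under the same setting and 0.038 without the 2 libraries and 5xFAD 2.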

Other observations

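Values without the libraries labelled WT 3 and Kcnip3 KO-5xFAD 2 were chosen after the data were seen; the list tests on all 12 libraries were planned.

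Nuclear-encoded oxidative phosphorylation genes were higher in 39 of 43 cases in 5xFAD against WT with a median of 0.20, and 1 rose, the complex III subunit gene Uqcr11 (0.52, adjusted p = 0.0460). The list passed camera (adjusted p = 3.9e-06), with an adjusted p = 0.555 with an estimated correlation. Myelin and oligodendrocyte genes were higher in 20 of 21 cases with a median of 0.51, and 1 rose, the transferrin gene Trf (0.96; list adjusted p = 0.551 with an estimated correlation). Markers of cortex, striatum and thalamus had a median of -0.45 with Rorb (-0.85) the called member, and circadian and glucocorticoid-regulated genes a median of -0.20 with the clock repressor gene Nr1d2 (-0.77) called, each with an adjusted p = 0.551 with an estimated correlation. Reported KChIP3 (DREAM) targets had a median of -0.34 (camera adjusted p = 0.0047, adjusted p = 0.399 with an estimated correlation), and meninges and fibroblasts -0.37 (adjusted p = 0.635 with an estimated correlation). In Kcnip3 KO-5xFAD against Kcnip3 KO the median of the DREAM targets was -0.08 and their mean 0.12, and they did not pass. Markers of the hippocampal fields did not pass in 5xFAD against WT, with medians of 0.31 for dentate granule neurons, 0.43 for CA1 and 0.39 for CA2 and CA3 pyramidal neurons, where the kainate receptor gene Grik4 rose (0.65). Nor did the Kv4 channel complex and KChIP relatives (median -0.24), calcium handling (-0.10), GABAergic interneurons (-0.12), amyloid precursor processing (0.07), the unfolded protein response (0.07), cholesterol synthesis (-0.04), astrocyte identity (0.15), oligodendrocyte precursors (0.15), endothelial and mural cells (0.19), blood cells (-0.46), choroid plexus (0.92) or adult neurogenesis (-0.11). Without the 2 libraries the medians of the last 3 lists were -0.26, 0.43 and -0.20, that of cholesterol synthesis 0.11 and that of meninges and fibroblasts -0.57. In the same fit that of endothelial and mural cells was -0.018 and that of the Kv4 channel complex and KChIP relatives -0.15.

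Adult neurogenesis genes had a median of 0.14 and a mean of 0.78 in Kcnip3 KO-5xFAD against 5xFAD, and 4 of 13 rose when adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.513 with an estimated correlation). The median was 0.08 without the 2 libraries, where the list did not pass camera (adjusted p = 0.0625). Igfbpl1, a gene of young neurons, was at 2.41 ± 1.16 against 0.308 ± 0.279 CPM (2.78, adjusted p = 0.323). Eomes, a transcription factor of intermediate progenitors, was at 16.4, 2.89 and 2.58 CPM in Kcnip3 KO-5xFAD and at 0.762, 0 and 0.0905 CPM in 5xFAD (4.68, adjusted p = 0.411). With the replicate block Eomes was the only gene called for the interaction (7.02 ± 0.78, adjusted p = 0.0155), where Fabp7 did not pass (adjusted p = 0.745).

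Choroid plexus transcripts varied between libraries of the same group. Ttr, the transthyretin gene, was at 83.5 CPM in the library labelled WT 3, 203 in 5xFAD 2, 341 in Kcnip3 KO-5xFAD 1 and 371 in Kcnip3 KO-5xFAD 2, and between 2890.0 and 8724 CPM in the other 8 libraries. The choroid plexus list had a median of 0.72 in Kcnip3 KO against WT and -0.95 in Kcnip3 KO-5xFAD against Kcnip3 KO (adjusted p = 0.612 and 0.690 with an estimated correlation). These medians were 0.33 and -0.50 without the 2 libraries, and the former did not pass camera there.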
